A study of Mus musculus with 22 samples.

How the data were processed

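Bulk RNA was measured in CD45-negative and CD45-positive cells of EMT6 tumours. Per the labels, 200000 cells were placed in both inguinal fat pads of BALB/c mice aged 5 to 6 weeks, JQ1 was given daily at 50 mg/kg, and paclitaxel and anti-PD-L1 at 10 mg/kg each in 2 injections a week. Per the submitters' processing notes, libraries came from low-input SMARTer kits and were aligned with STAR 2.5.1b to mm9. The tool that made the gene values and its version are not given in the sources used here. The series' chromatin accessibility libraries were not used here. Samples were grouped by fraction and treatment as the labels give them.

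The 2 deposited tables, 1 per fraction, hold FPKM. This unit was inferred from the values, although the label of each table speaks of counts: the values have decimals, and columns sum to 296682 to 370513 in the CD45-negative and 315256 to 364118 in the CD45-positive table. Each table holds 24353 symbols, of which 23458 were matched to mouse gene symbols. In every library 7440 of them were 0 in the CD45-negative fraction and 7124 in the CD45-positive fraction. The annotation at hand was of a newer build, so no coordinates were used. Values of near-identical genes (globins, proliferins, ferritin and histone copies) depend on how shared reads were assigned. No columns were left out.

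FPKM hold no read totals. In each library the lowest values are multiples of a step set by 1 read, and steps of the same genes were compared between libraries (66 and 45 library pairs, of which 3 CD45-negative ones were read at another multiple, and 1950 and 1856 genes), which gave relative depths with a largest residual of 0.00435 log2. At these depths 84.9% and 86.6% of low values lay within 0.05 steps of whole multiples, against 10.2% and 10.4% after multiplication by random factors. On 10 simulated libraries the largest error was 6.66e-16 log2. Absolute depth, and with it the counting error of each gene, stayed unknown, so precision was taken from the spread between libraries: log2 values correlated across genes at 0.968 to 0.983 within CD45-negative and 0.938 to 0.977 within CD45-positive groups.

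Genes with at least 1 FPKM in at least 2 libraries of a fraction were kept (10780 CD45-negative and 10340 CD45-positive). For each fraction 1 limma model with a mean-variance trend was fitted to log2(FPKM + 1) of the 5 groups (7 and 5 residual degrees of freedom, 12.8 and 8.94 after moderation), with R 4.3.3 and limma 3.58.1. DESeq2 and edgeR were not used, as they need counts. The fractions were not tested against each other. The 8 comparisons per fraction were each treated group against vehicle, the mean of the 4 treated groups against vehicle, the mean of the 2 groups with paclitaxel or anti-PD-L1 against the mean of the 2 treated groups without it, and the interaction of the 2 drugs. Tests were two-sided, with Benjamini-Hochberg adjusted p under 0.05 over the genes of a comparison. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

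The comparisons, the rule for naming genes and 35 gene lists were fixed before the data were examined. The lists were BET inhibitor reporters, MYC targets and ribosome biogenesis, G2/M and mitosis, DNA replication, p53 targets, apoptosis regulators, tubulins and paclitaxel-related genes, type I interferon response, interferon gamma response, MHC class I and class II presentation, T cells, cytotoxic effectors, T cell checkpoint and exhaustion, regulatory T cells, NK cells, B and plasma cells, neutrophils, macrophages and monocytes, alternatively activated macrophages, inflammatory cytokines, dendritic cells, mast cells with basophils and eosinophils, pan-leukocyte, fibroblasts and collagens, endothelial cells, pericytes, adipocytes, skeletal muscle, epithelium, erythroid cells, mesenchymal transition and matrix, hypoxia and glycolysis, immediate early and dissociation stress, and unfolded protein and amino acid stress. Lists with at least 3 tested members were tested with camera at a preset correlation of 0.01, and also with the estimated correlation and with fry, adjusted over the lists of a comparison. Named genes were the 8 highest and 8 lowest fold changes (5 and 5 for single groups and the interaction) among called genes with mean log2(FPKM + 1) of at least 2 and no overlap between the compared libraries, clone identifiers passed over, filled to 4 each way by p; up to 3 called members of each list, or else the 2 of highest level; and Myc, Hexim1, Cd274 and Ptprc. Of the genes that this rule names, 1 is not reported here. Histone genes were taken as a group after their values were seen.

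The test was checked on simulated data, 5 sets of 200 changed genes. In the CD45-negative JQ1 comparison it recovered 53.8% of log2 changes of 1 and 94.6% of changes of 2, with 4.7% of calls false. For anti-PD-L1 added these were 85.8%, 99% and 5.03%. In the CD45-positive fraction they were 19.8%, 73.2% and 2.72% for JQ1 and 51.8%, 90.6% and 4% for anti-PD-L1 added. False shares hold for the simulated noise, not for effects shared within a mouse code. No recovered sign was wrong.

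The alternatives tried were a pseudocount of 0.1, no filter, libraries rescaled by the median of ratios, correlation between tumours of 1 mouse code, a single value per mouse code, and leaving out each library in turn. Leaving out the genes of the other fraction (those with a higher mean FPKM in its table) and log2 relative depth as a covariate were added after the data were seen.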

Results

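Bulk RNA sequencing of 22 libraries measured gene expression in EMT6 tumours, grown from a mouse mammary carcinoma line in the mammary fat pads of BALB/c mice. Dissociated tumours were separated with beads against CD45, a protein on the surface of leukocytes, and the 2 fractions were sequenced apart. The CD45-negative fraction, enriched for tumour cells, held 12 libraries, of which 2 came from vehicle-treated tumours, 2 from JQ1, 2 from JQ1 with anti-PD-L1, 3 from JQ1 with paclitaxel and 3 from all 3 drugs (the 3-drug group). The CD45-positive fraction, enriched for leukocytes, held 10 libraries, 2 in each of the 5 groups. JQ1 blocks BET bromodomain proteins, which bind acetylated histones at enhancers and promoters. Paclitaxel stabilises microtubules, and anti-PD-L1 is an antibody against the ligand of the T cell checkpoint receptor PD-1. No group received paclitaxel or anti-PD-L1 without JQ1, so both drugs were examined only on top of JQ1. The vehicle, JQ1 and JQ1 with anti-PD-L1 groups carried 1 mouse code each, with a right and a left tumour. The labels do not spell the code out, so the p-values measure spread between tumours that may come from a single animal.

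The values were FPKM, which give no read totals, so absolute depth was unknown. Steps between low values gave the depth of each library relative to the geometric mean of its fraction. In the CD45-negative fraction it was 1.79 and 1.13 for vehicle, 0.554 and 0.653 for JQ1, 1.39 and 1.02 for JQ1 with anti-PD-L1, 1.45, 0.547 and 1.58 for JQ1 with paclitaxel, and 0.794, 1.01 and 0.963 for the 3-drug group. In the CD45-positive fraction it was 1.3 and 1.44 for vehicle, 0.862 and 1.28 for JQ1, 0.739 and 0.672 for JQ1 with anti-PD-L1, 0.905 and 0.629 for JQ1 with paclitaxel, and 1.72 and 1 for the 3-drug group. Depth was therefore partly tied to group, with both CD45-negative JQ1 libraries shallower than both vehicle libraries.

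Leukocyte genes separated the fractions. Ptprc, which encodes CD45, lay between 1.25 and 8.65 FPKM in the CD45-negative libraries and between 38.6 and 73.6 FPKM in the CD45-positive libraries of the same 10 tumours. The summed FPKM of 12 pan-leukocyte genes in the CD45-negative library was 6.21% to 14.9% of that in the CD45-positive library of the same tumour (median 9.56%). Fibroblast and collagen genes in the CD45-positive fraction reached 1.87% to 13.9% of their CD45-negative sum, with the highest shares, 9.75% and 13.9%, in JQ1 with paclitaxel. The fractions were not tested against each other. The first principal component of the CD45-negative libraries (35.6% of the variance) set JQ1 and JQ1 with paclitaxel, at 10.3 to 35.3, apart from vehicle at −16.9 and −23.8, JQ1 with anti-PD-L1 at −3.51 and −14.4, and the 3-drug group at −20.5 to −26.9. On the second component (17.6%) vehicle lay at 22.7 and 19.2 and the 3-drug group at −12.2, −26.8 and −10.5. In the CD45-positive fraction the first component (30.1%) ran from vehicle at −31.8 and −27.5 to JQ1 with paclitaxel at 32 and 31.3, and the second (21.3%) set JQ1 replicate 1 apart at −45.8.

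**Figure D1:**
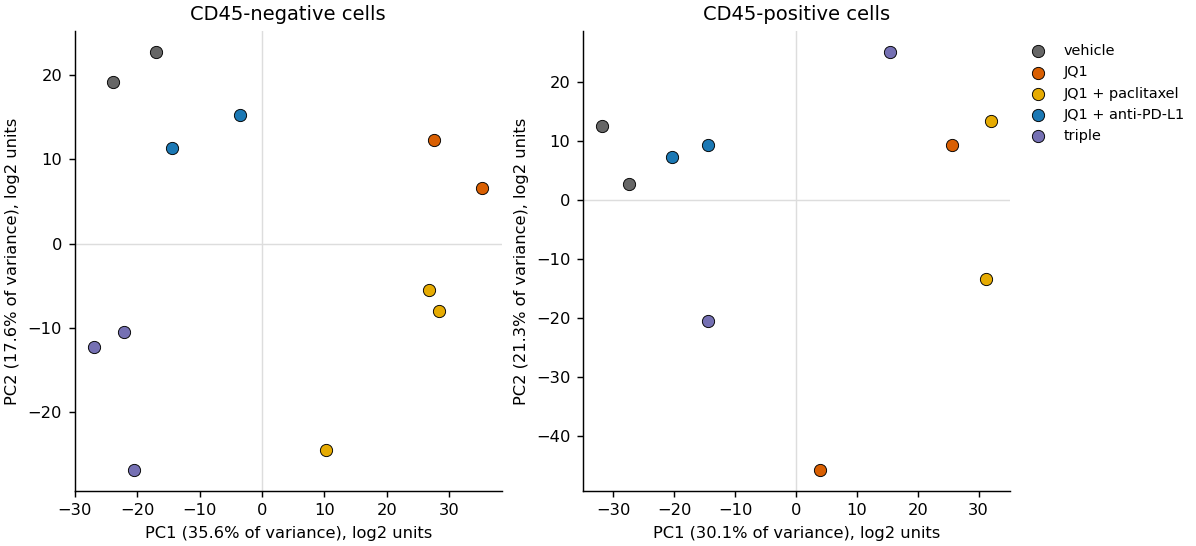
Scores of each library on the first and second principal components of log2(FPKM + 1), with 12 CD45-negative libraries on the left and 10 CD45-positive libraries on the right, coloured by treatment group. The CD45-negative JQ1 and JQ1 with paclitaxel libraries lie at 10.3 to 35.3 on the first component and every other library there lies below 0.

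Fold changes below are differences of log2(FPKM + 1) ± standard error, which understate the change of low genes. A gene is said to have risen or fallen where limma's adjusted p was under 0.05. Lists of genes fixed beforehand were tested with camera at a preset correlation between genes, and a bracketed pair after a list gives its median and camera's adjusted p. No list call in any comparison held with an estimated correlation, so each list call is given with that second value.

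In CD45-negative cells the 4 treated groups (n = 10 libraries) were first set against vehicle (n = 2). Haemoglobin transcripts of red blood cells fell furthest, HBB-B1 (−4.46 ± 0.42, adjusted p = 0.000259), Hba-a1 (−4.82 ± 0.80, adjusted p = 0.00493) and Hbb-bt (−4.05 ± 0.38, adjusted p = 0.000259). Near-identical globin copies share reads, so the split between them is uncertain. Mgp (−2.64 ± 0.45), Omd (−2.63 ± 0.37), Angpt4 (−2.36 ± 0.25), Plac9a (−2.02 ± 0.44) and Serpinf1 (−1.92 ± 0.31), which encode secreted proteins, fell, with adjusted p from 0.000637 to 0.0169. The fibroblast and collagen list (median −0.10, mean 0.01, camera adjusted p = 0.824) was not called. The alarmin Il33 fell by 2.16 ± 0.16 (adjusted p = 7.26e-05) and the glutathione transferase gene Gstt1 by 1.91 ± 0.21 (adjusted p = 0.000637). The chemokine genes Ccl3 (1.90 ± 0.32) and Ccl4 (1.40 ± 0.34) rose, as did Cyp1b1 (1.54 ± 0.41), and Wfdc17 (1.54 ± 0.28), Plek (1.45 ± 0.31) and Sirpa (1.28 ± 0.31), which are expressed in myeloid cells. Abtb2 (1.3 ± 0.19) and Sema7a (1.28 ± 0.21) completed the 8 highest, and adjusted p for the 8 ran from 0.0029 to 0.0387. Of 22 G2/M and mitosis genes, 3 fell, the kinase gene Plk1 (−1.04 ± 0.19), the cyclin gene Ccnb2 (−0.94 ± 0.19) and Aurka (−0.56 ± 0.14), and 11 fell adjusted over the list alone. That list (median −0.44, 0.000102) had adjusted p = 0.824 with an estimated correlation. Of 4 erythroid genes 3 fell (median −4.26, 9.3e-05, or 0.435 with an estimated correlation). Endothelial (median 0.54, 0.0025), pan-leukocyte (0.64, 0.00583), inflammatory cytokine (0.47, 0.0251), interferon gamma (0.40, 0.0381) and macrophage (0.30, 0.04) lists were higher, each with adjusted p = 0.824 with an estimated correlation. Mean macrophage levels were higher mainly with antibody (5.22, and 3-drug 4.63, vehicle 4.31, JQ1 4.35, JQ1 with paclitaxel 4.28). Mitotic levels were lowest with paclitaxel (3.17, and 3-drug 3.57, vehicle 4.07, JQ1 3.82, JQ1 with anti-PD-L1 3.98). In JQ1 alone the interferon gamma and inflammatory means were −0.17 and −0.68. The macrophage mean turned to −0.119 (camera adjusted p = 0.951) with relative depth as a covariate, and the inflammatory mean was −0.352 (0.985) without the genes higher in the CD45-positive fraction. Of these higher lists, only the inflammatory one held genes past the threshold, Ccl3, Ccl4 and Ccl7 (0.78 ± 0.21, adjusted p = 0.0415). Members of other lists past it were the interferon gene Usp18 (−0.77 ± 0.17) and Bst2 (−0.65 ± 0.13), the pro-apoptotic gene Bcl2l11 (1.28 ± 0.28), the stress gene Sesn2 (1.13 ± 0.22), the epithelial gene Trp63 (−1.42 ± 0.18) and the muscle actin gene Acta2 (−0.98 ± 0.19). Hexim1, a known reporter of BET inhibition, rose by 0.72 ± 0.19 (adjusted p = 0.0364) with libraries of the groups overlapping, while Myc (−0.02 ± 0.30), Cd274 (0.75 ± 0.42) and Ptprc (0.97 ± 0.35) were not past the threshold. In all, limma called 794 of 10780 genes, 189 higher and 605 lower. The count fell to 118 without vehicle replicate 1, to 57 without vehicle replicate 2, to 332 with log2 relative depth as a covariate (309 of them among the 794) and to 10 with a single value per mouse code.

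**Figure D2:**
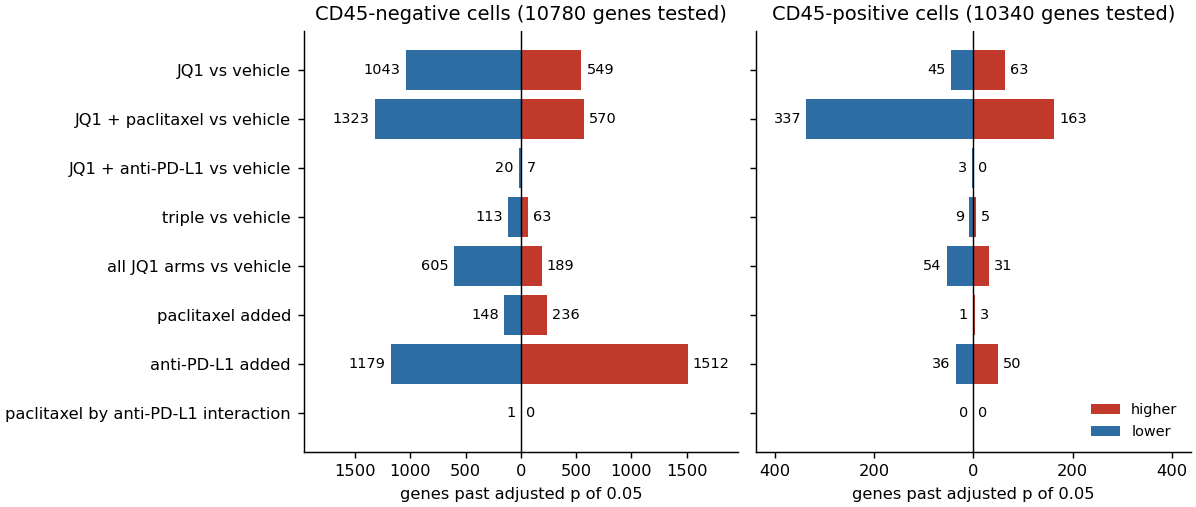
Number of genes higher (bars to the right) and lower (bars to the left) at limma's adjusted p under 0.05 in each of the 8 comparisons, for the CD45-negative and the CD45-positive fraction. The highest counts are 2691 for anti-PD-L1 added, 1893 for JQ1 with paclitaxel and 1592 for JQ1, all in the CD45-negative fraction.

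JQ1 alone against vehicle (n = 2 and 2) asked what BET inhibition did by itself. Brd2, a gene of a BET protein that JQ1 binds, rose by 2.27 ± 0.33 (adjusted p = 0.00152) and Hexim1 by 1.2 ± 0.24 (adjusted p = 0.0076), from 1.07 ± 0.432 to 3.71 ± 0.522 FPKM (mean ± SD). The histone gene Hist3h2a rose by 2.30 ± 0.32 (adjusted p = 0.00119). Of 55 tested histone genes, a set defined after their values were seen, 21 rose and the other 34 were not past the threshold. Neat1 (2.20 ± 0.55), Chchd7 (1.97 ± 0.23) and Txnip (1.90 ± 0.49) also rose, with adjusted p from 0.0005 to 0.0229. HBB-B1 (−5.24 ± 0.54), the proliferin genes Prl2c2 (−4.28 ± 0.78) and PRL2C4 (−3.89 ± 0.70), the potassium channel gene Kcnn4 (−3.74 ± 0.45) and Omd (−3.56 ± 0.48) fell, with adjusted p from 0.00034 to 0.00439. Proliferin copies are near-identical and share reads. Type I interferon genes fell, 7 of 24, or 10 adjusted over the list alone, led by Ifit3 (−1.81 ± 0.23), Ifi44 (−1.17 ± 0.33) and Usp18 (−1.05 ± 0.22). Their median was −0.58, and that of the erythroid list −4.96 (3 of 4 lower), each with camera adjusted p = 0.00117 (0.925 and 0.798 with an estimated correlation). Of 7 BET inhibitor reporters 2 rose (Hexim1 and Hist1h2bk, 0.93 ± 0.29) and 2 fell, led by Ccr2 (−1.79 ± 0.32). With both directions, the median (−0.55) and camera adjusted p (0.977) cannot judge the list. MHC class I presentation lost 4 of 13 genes, such as Tap2 (−0.87 ± 0.15) and Psmb10 (−0.70 ± 0.20), with 6 lower adjusted over the list alone and a camera adjusted p = 0.0501. Other lists had members past the threshold without a list call. They included the neutrophil chemokine genes Cxcl5 (−3.46 ± 0.55) and Cxcl1 (−1.64 ± 0.29), the growth factor gene Csf3 (−2.83 ± 0.75), and the epithelial genes Trp63 (−2.10 ± 0.23) and Krt18 (−1.75 ± 0.44). Further such genes were the p53 targets Bbc3 (−1.64 ± 0.31) and Fas (−1.14 ± 0.22), and the T cell gene Tcf7 (−1.46 ± 0.20). The hypoxia list had 1 gene lower, Egln3 (−1.08 ± 0.33), of 17 (median −0.35, camera adjusted p = 0.069), and the mesenchymal transition list 1 higher and 4 lower, led by Tgfb2 (−1.47 ± 0.35), of 18 (median −0.27, camera adjusted p = 0.455). Myc (−0.56 ± 0.38, adjusted p = 0.336) was not past the threshold. The total was 1592 genes, 549 higher and 1043 lower. It moved to 684 and 455 without vehicle replicate 1 and 2, to 423 without JQ1 replicate 1, to 21 with a single value per mouse code, and to 321 with relative depth as a covariate, when 9 histone genes were higher (histone median 0.77, against 0.66 without the covariate).

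**Figure D3:**
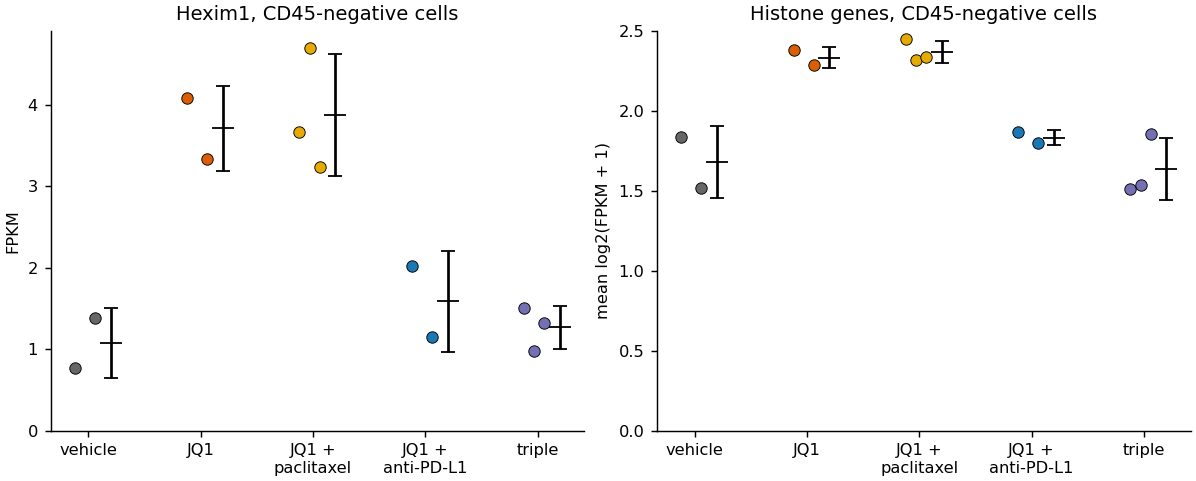
Hexim1 in FPKM (left) and the mean log2(FPKM + 1) of 55 histone genes (right) in each CD45-negative library, with the group mean and SD as line and bar. Hexim1 lies at 3.24 to 4.7 FPKM in the 5 libraries given JQ1 alone or with paclitaxel and at 0.768 to 2.02 FPKM in the 7 others.

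JQ1 with anti-PD-L1 against vehicle (n = 2 and 2) gave few calls. Myeloid or platelet genes rose, Pf4 (2.74 ± 0.45), Wfdc17 (2.60 ± 0.36), Ccl6 (2.57 ± 0.35) and Ccl7 (1.98 ± 0.27), together with Pdpn (1.2 ± 0.17) and the mannose receptor gene Mrc1 (1.54 ± 0.28, adjusted p = 0.0447). The glucocorticoid-induced gene Tsc22d3 (−2.45 ± 0.37), the Wnt inhibitor gene Notum (−2.21 ± 0.27), Gstt1 (−1.70 ± 0.26), the heat shock gene Hspb1 (−1.70 ± 0.28) and Rerg (−1.59 ± 0.23) fell, and adjusted p for the 5 highest and 5 lowest genes ran from 0.00611 to 0.0269. Macrophage and monocyte genes had a median of 0.85, with 6 of 18 higher adjusted over the list alone (camera adjusted p = 4.66e-08, or 0.53 with an estimated correlation). Alternatively activated macrophage (median 1.17, 5 of 8 adjusted over the list alone), pan-leukocyte (1.04, 5 of 12) and inflammatory cytokine genes (0.93, 9 of 20) each had a camera adjusted p = 5.36e-06, and adjusted p = 0.389 to 0.53 with an estimated correlation. The inflammatory mean turned to −0.349 (camera adjusted p = 0.926) without the genes higher in the CD45-positive fraction. Neutrophil genes (median 0.51, camera adjusted p = 0.000738), type I interferon genes (0.27, 0.0172) and endothelial genes (0.43, 0.0329) were also higher, and MHC class I (−0.34, 0.00075), erythroid (−1.84, 0.00373), immediate early (−0.48, 0.014) and epithelial genes (−0.54, 0.0172) lower. These 7 lists had adjusted p = 0.53 to 0.679 with an estimated correlation. Hexim1 was 1.59 ± 0.616 FPKM (0.31 ± 0.24, adjusted p = 0.603), and histone genes had a median of 0.14 with none past the threshold. In total 27 genes were called, 7 higher and 20 lower, and 1554 had an unadjusted p under 0.05. The count was 5 and 2 without vehicle replicate 1 and 2, 1 and 12 without JQ1 with anti-PD-L1 replicate 1 and 2, 16 without 3-drug replicate 1, and 57, 76 and 104 without JQ1 with paclitaxel replicate 1, 2 and 3.

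With paclitaxel added to JQ1 (n = 3 against 2 vehicle libraries), histone genes again led the rise, Hist2h2aa1 by 2.58 ± 0.19 (adjusted p = 3.59e-05), Hist3h2a by 2.12 ± 0.29 and Hist1h2bg by 2.11 ± 0.22, and 28 of 55 histone genes rose and 4 fell. Ccl3 (2.39 ± 0.38, adjusted p = 0.00156) and Cyp1b1 (2.06 ± 0.48, adjusted p = 0.0122) rose as well. HBB-B1 (−5.62 ± 0.49), Prl2c2 (−3.95 ± 0.71), PRL2C4 (−3.58 ± 0.64), Angpt4 (−3.29 ± 0.30) and Mgp (−3.23 ± 0.53) fell, with adjusted p from 6.45e-05 to 0.00334. Mitotic genes fell, 16 of 22, or 19 adjusted over the list alone, with Plk1 at −1.78 ± 0.22, Ccnb2 at −1.61 ± 0.23 and Ube2c at −1.43 ± 0.25. Their median was −0.93 (camera adjusted p = 1.31e-09). DNA replication genes such as Cdc45 (−1.01 ± 0.26) and the helicase gene Mcm3 (−0.97 ± 0.19) fell, 8 of 21, or 11 adjusted over the list alone (median −0.37, 0.000999). Type I interferon genes had 8 of 24 lower, or 11 adjusted over the list alone, led by Usp18 (−1.77 ± 0.20; median −0.51, camera adjusted p = 0.00144). MYC target and ribosome biogenesis genes had 4 of 22 lower, such as the spermidine synthase gene Srm (−0.95 ± 0.17; median −0.35, camera adjusted p = 0.0261), and hypoxia and glycolysis genes 3 of 17, or 4 adjusted over the list alone, such as Adm (−1.78 ± 0.34; median −0.42, camera adjusted p = 0.0261). Endothelial genes were higher, with Eng at 1.23 ± 0.34 (adjusted p = 0.027), 3 of 10 adjusted over the list alone and a median of 0.91 (camera adjusted p = 0.00144). Interferon gamma genes had a median of 0.63 (camera adjusted p = 0.00644) with no member past the threshold. Erythroid genes had 3 of 4 lower (median −5.12, 0.00052). These 8 lists had adjusted p = 0.725 to 0.729 with an estimated correlation. The tubulin list moved both ways, Tubb4b (1 ± 0.26) and Tuba1c (0.97 ± 0.21) higher and the microtubule destabiliser gene Stmn1 (−0.96 ± 0.19) lower, with a camera adjusted p = 0.0802. The BH3-only gene Bcl2l11 rose by 2.02 ± 0.32 (adjusted p = 0.00173), and Hexim1 by 1.24 ± 0.22 (adjusted p = 0.00309) to 3.87 ± 0.751 FPKM (n = 3). The adipocyte list had a median of −0.64 (camera adjusted p = 0.825) with Fabp4 (1.79 ± 0.46) higher and Retn (−1.41 ± 0.43) lower, and skeletal muscle genes had a median of −0.06 and a mean of 0.09 (camera adjusted p = 0.825) with Mylpf (1.17 ± 0.35) higher. A total of 1893 genes was called, 570 higher and 1323 lower. It was 821 and 530 without vehicle replicate 1 and 2 and 274 with a single value per mouse code.

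The 3-drug group against vehicle (n = 3 and 2) had fewer calls than JQ1 with paclitaxel. The amino acid and unfolded protein stress genes Chac1 (3.22 ± 0.65, adjusted p = 0.0455), Sesn2 (1.97 ± 0.26, adjusted p = 0.00771) and Trib3 (1.38 ± 0.30, adjusted p = 0.0459) rose, and so did the cell cycle inhibitor gene Cdkn1a (1.42 ± 0.22, adjusted p = 0.0213). Cyp1b1 (2.99 ± 0.48), the itaconate synthase gene IRG1 (2.88 ± 0.58), the interferon-induced GTPase gene Gbp4 (2.09 ± 0.47) and the macrophage elastase gene Mmp12 (2.01 ± 0.40) were the other highest genes. The lowest were HBB-B1 (−5.17 ± 0.49), Mgp (−2.36 ± 0.53), the neutrophil gelatinase gene Mmp9 (−2.22 ± 0.28), C1qtnf3 (−2.18 ± 0.46) and Stra6 (−2.18 ± 0.48). Interferon gamma genes (median 1.01, 5.59e-08) had Gbp3 (1.15 ± 0.26) past the threshold and 6 of 17 adjusted over the list alone. Inflammatory genes (0.83, 1.72e-07) had 9 of 20, MHC class II genes (1.85, 3.25e-06) 7 of 8, unfolded protein genes (0.40, 1e-05) 7 of 14 higher and 1 lower, and p53 targets (0.23, 0.000167) 7 of 18, all adjusted over the list alone. These 5 lists had adjusted p = 0.109 to 0.375 with an estimated correlation. Mitotic genes (−0.53, 1.23e-06) had Plk1 (−1.05 ± 0.22) and Ccna2 (−0.83 ± 0.17) lower and 10 of 22 lower adjusted over the list alone. Immediate early genes had a median of −0.73 (0.000425), with Dusp1 (−1.82 ± 0.30) and Dnajb1 (−1.03 ± 0.24) lower. Erythroid genes (−4.93, 2.7e-06) were lower, and pan-leukocyte (0.74, 4.7e-05), endothelial (0.74, 0.000194), type I interferon (0.19, 0.00134), macrophage (0.44, 0.012), T cell checkpoint (0.59, 0.0327), MYC target (0.11, 0.0424) and tubulin genes (0.13, 0.0424) higher. These 10 lists had adjusted p = 0.146 to 0.673 with an estimated correlation. The macrophage mean was −0.108 with relative depth as a covariate, and the MYC target mean −0.0383 without vehicle replicate 1. Hexim1 was 1.27 ± 0.268 FPKM (0.14 ± 0.22), histone genes had a median of −0.04 with none past the threshold, and Cd274, the PD-L1 gene, stood at 1.81 ± 0.49 (adjusted p = 0.0756). The 176 calls comprised 63 higher and 113 lower, and 65 higher and 57 lower of 122 after rescaling of the libraries. The count was 5 and 30 without vehicle replicate 1 and 2, 57 and 10 without 3-drug replicate 1 and 2, 72 without either JQ1 library, 49 without either JQ1 with anti-PD-L1 library, 322 without JQ1 with paclitaxel replicate 3, and 48 with relative depth as a covariate.

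These comparisons share their vehicle libraries. JQ1 alone and JQ1 with paclitaxel had 285 genes higher and 727 lower in common, against 29 and 128 for independent lists, and 1 gene went opposite ways. Their fold changes correlated across genes at r = 0.804 (covariance 0.24), where unchanged groups simulated against the same controls gave 0.548 (covariance 0.0415). JQ1 alone and the 3-drug group shared 11 higher and 62 lower genes, against 3.21 and 10.9 for independent lists (r = 0.297, covariance 0.0699, against 0.546 and 0.0412 without effect). Against separate vehicle libraries, 1 for each comparison, r was 0.63 or 0.62 for the first pair (covariance 0.208 or 0.206) and 0.214 or 0.0724 for the second (covariance 0.0534 or 0.0208), depending on which library went to which. Genes are not independent replicates, and part of the overlaps of called genes may come from the shared vehicle libraries.

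Paclitaxel added to JQ1 in CD45-negative cells set the 6 libraries with paclitaxel against the 4 without, each group weighing equally. Interferon gamma genes rose, 7 of 17, or 12 adjusted over the list alone, with the GTPase genes Igtp (1.71 ± 0.34, adjusted p = 0.0238) and Iigp1 (1.72 ± 0.42, adjusted p = 0.0443), and with Cd274 (1.42 ± 0.35, adjusted p = 0.0438). Gbp4 (1.78 ± 0.33), Cyp1b1 (1.97 ± 0.34), Ippk (1.5 ± 0.27), Ncmap (1.24 ± 0.16) and the immediate early gene Arc (1.23 ± 0.18) rose too, with adjusted p from 0.00484 to 0.018. Pf4 (−2.79 ± 0.29), the neutrophil gene S100a9 (−2.27 ± 0.22) and Mmp9 (−1.22 ± 0.20) fell. So did Acta2 (−1.15 ± 0.16), Ccna2 (−1.08 ± 0.12), the collagen gene Col5a2 (−1.03 ± 0.20), Cxcl14 (−0.93 ± 0.15) and Csrp2 (−0.88 ± 0.16), with adjusted p from 0.000823 to 0.0192. Mitotic genes fell, 9 of 22, or 18 adjusted over the list alone, including Bub1 (−0.81 ± 0.14) and Plk1 (−0.75 ± 0.15) (median −0.49, 3.07e-13). Replication genes had 3 of 21 lower, such as Mcm6 (−0.45 ± 0.09), or 9 adjusted over the list alone, with 1 higher there (median −0.28, 3.82e-05). The interferon gamma median was 0.94 (1.29e-09), MHC class I had 4 of 13 higher, such as Tapbp (0.51 ± 0.11) and H2-K1 (0.41 ± 0.10), and 7 adjusted over the list alone (median 0.27, 1.24e-05). MHC class II had 2 of 8 higher, Cd74 (1.88 ± 0.43) and H2-DMa (0.94 ± 0.23), and 6 adjusted over the list alone (median 1.33, 3.06e-05). H2-K1 is polymorphic in BALB/c, which affects its mapping. Targets of p53 rose, 5 of 18, with Bbc3 (1.46 ± 0.20) and Mdm2 (1.05 ± 0.22), and 7 adjusted over the list alone (median 0.19, 3.82e-05, or 0.0662 with an estimated correlation). Tubulin genes had 3 of 16 higher, Tubb2a (0.85 ± 0.14), Tubb2b (0.84 ± 0.14) and the drug exporter gene Abcb1a (0.80 ± 0.18), and 5 adjusted over the list alone (median 0.21, 0.000316). Inflammatory genes (median 0.49, 0.000114) rose in Cxcl5 (1.73 ± 0.36) and fell in Ccl7 (−0.75 ± 0.17). Neutrophil (−0.22, 0.0233, 4 lower adjusted over the list alone), alternatively activated macrophage (−0.73, 0.0149, 5), erythroid (−1.23, 0.0132, 2) and immediate early genes (−0.22, 0.0149, 4) were lower. Epithelial (0.46, 0.00571), endothelial (0.31, 0.0229) and apoptosis regulator genes (0.19, 0.0233) were higher. Apart from p53 targets, these lists had adjusted p = 0.32 to 0.642 with an estimated correlation. MHC class II, neutrophil and alternatively activated macrophage levels moved mainly with antibody (MHC class II 3.94 to 6.14, without it 4.11 to 4.34). Replication and inflammatory levels moved mainly without it. Myc was at 0.94 ± 0.25 (adjusted p = 0.0543). A total of 384 genes was called, 236 higher and 148 lower. It was 137 without 3-drug replicate 2, 200 without JQ1 with paclitaxel replicate 3, 29 and 111 without JQ1 replicate 1 and 2, and 8 and 220 without JQ1 with anti-PD-L1 replicate 1 and 2. It was 120 without a filter on low values (56 higher and 64 lower), 7 with a single value per mouse code and 231 with relative depth as a covariate.

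Anti-PD-L1 added to JQ1, the 5 libraries with antibody against the 5 without, gave the most calls. Histone genes fell, 28 of 55, with 5 higher, and they supplied most of the 8 lowest genes. These were Hist1h2bc (−2.50 ± 0.14, adjusted p = 1.17e-06), Hist3h2a (−2.44 ± 0.21), Hist2h2aa1 (−2.20 ± 0.14), Hist1h2bg (−2.10 ± 0.16), Hist1h2be (−1.91 ± 0.21), Hist1h2bq (−1.83 ± 0.16) and Hist1h1c (−1.71 ± 0.18), beside Habp4 (−1.77 ± 0.09, adjusted p = 7.2e-07). Hexim1 fell by 0.99 ± 0.16 (adjusted p = 0.00103) and Ccr2 rose by 1.23 ± 0.20 (adjusted p = 0.00132). Myeloid genes led the rise, the chemokine genes Ccl12 (2.47 ± 0.21, adjusted p = 2.9e-05) and Cxcl3 (1.92 ± 0.28), the interleukin-1 antagonist gene Il1rn (2.47 ± 0.32), the lectin receptor genes Clec4n (2.31 ± 0.26) and Clec4d (1.97 ± 0.16) and the arginase gene Arg1 (1.76 ± 0.26). WISP2 (2 ± 0.25) and Tnnt2 (1.79 ± 0.28) rose too, and adjusted p for the 8 reached at most 0.00098. The pan-leukocyte sum moved with these genes: it was 11% to 14.9% of its CD45-positive value in the 4 tumours with antibody that had both fractions and 7.49% to 10.6% in the 4 given JQ1 without it. Type I interferon genes rose, 19 of 24, or 20 adjusted over the list alone, with Ifit3 (1.88 ± 0.15), Ifi44 (1.68 ± 0.22) and Usp18 (1.27 ± 0.14) in front (median 0.81, 8.03e-10, or 0.2 with an estimated correlation). MYC target genes rose, 14 of 22, or 15 adjusted over the list alone, such as Srm (0.91 ± 0.12) and the RNA polymerase I gene Polr1b (0.76 ± 0.18; median 0.45, camera adjusted p = 3.8e-05). Inflammatory genes rose, 9 of 20, or 11 adjusted over the list alone, such as Il1a (2.19 ± 0.34) and Il1b (2.11 ± 0.37; median 0.94, 1.87e-05), and immediate early genes fell, 9 of 17, such as Ier2 (−1.59 ± 0.27) and Fos (−1.14 ± 0.30; median −0.68, 1.67e-05). DNA replication had 10 of 21 higher, or 11 adjusted over the list alone, such as Cdt1 (0.84 ± 0.17; median 0.32, 0.00282), and mitosis 6 of 22, such as Ube2c (1.07 ± 0.18; median 0.23, 0.0183). Macrophage genes had 7 of 18 higher, such as Ly6c2 (1.65 ± 0.25; median 0.54, 0.00567), pan-leukocyte genes 3 of 12 (0.63, 0.00883) and neutrophil genes 4 of 12 (0.49, 0.00217). Alternatively activated macrophage genes had 3 of 8 higher (0.43, 0.0194), T cell checkpoint genes 3 of 4, such as Havcr2 (1.26 ± 0.16; median 1.07, 0.00512), and T cell genes 2 of 4, Lck (1.05 ± 0.27) and Tcf7 (0.67 ± 0.13; median 0.69, 0.0453). Hypoxia genes had 6 of 17 higher, such as Ndrg1 (1.22 ± 0.24; median 0.24, 0.0194), unfolded protein genes 5 of 14, such as Trib3 (1.19 ± 0.21; median 0.38, 0.0386), p53 targets 7 higher and 1 lower of 18 (0.29, 0.044) and erythroid genes 2 of 4 (1.39, 0.0455). In these last 10 lists the numbers adjusted over the list alone were the same but for macrophages (8), unfolded protein (7, and 1 lower) and p53 targets (9, and 2 lower). The 15 lists after the interferon list had adjusted p = 0.2 to 0.669 with an estimated correlation. Levels of replication (3.6 to 4.13) and unfolded protein genes (5.03 to 5.81) were higher mainly with paclitaxel (without it 4.1 to 4.18 and 5.15 to 5.14). Bcl2l11 fell by 0.72 ± 0.23 and Trp63 rose by 1.18 ± 0.15, while Cd274 (0.54 ± 0.35, adjusted p = 0.272) was not past the threshold. The 2691 calls comprised 1512 higher and 1179 lower. The count was 1567 without JQ1 with anti-PD-L1 replicate 2 and 738 with a single value per mouse code.

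Whether paclitaxel and anti-PD-L1 changed each other's effect was tested by their interaction on the JQ1 background. A single CD45-negative gene was called, the small nucleolar RNA gene Snora21 (−3.58, adjusted p = 5.57e-05), chosen after its value was seen, and 771 genes had an unadjusted p under 0.05. Aars (1.46 ± 0.21, adjusted p = 0.0533), Pck2 (1.24 ± 0.22), the amino acid transporter gene Slc7a5 (1.12 ± 0.20) and Asns (1.79 ± 0.33) stood highest without passing the threshold. Ppil3 (−1.44 ± 0.26), Wfdc17 (−2.55 ± 0.47), MYEOV2 (−1.11 ± 0.21) and S100a8 (−1.92 ± 0.38) stood lowest. Camera called 10 lists, with adjusted p = 0.286 to 0.664 with an estimated correlation. DNA replication (median 0.46, 1.66e-08), unfolded protein (0.69, 3.23e-06), MHC class II (2.47, 3.68e-06), MHC class I (0.26, 0.00317) and mitotic genes (0.28, 0.00401) were higher. Inflammatory (−0.99, 3.23e-06), alternatively activated macrophage (−1.17, 0.000138), erythroid (−2.15, 0.00103), neutrophil (−0.76, 0.0011) and macrophage genes (−0.34, 0.00755) were lower. Of the stress list, 7 of 14 were higher and 1 lower adjusted over the list alone. The single call was lost without JQ1 with anti-PD-L1 replicate 1, and 4 genes were called without JQ1 with paclitaxel replicate 3.

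**Figure D4:**
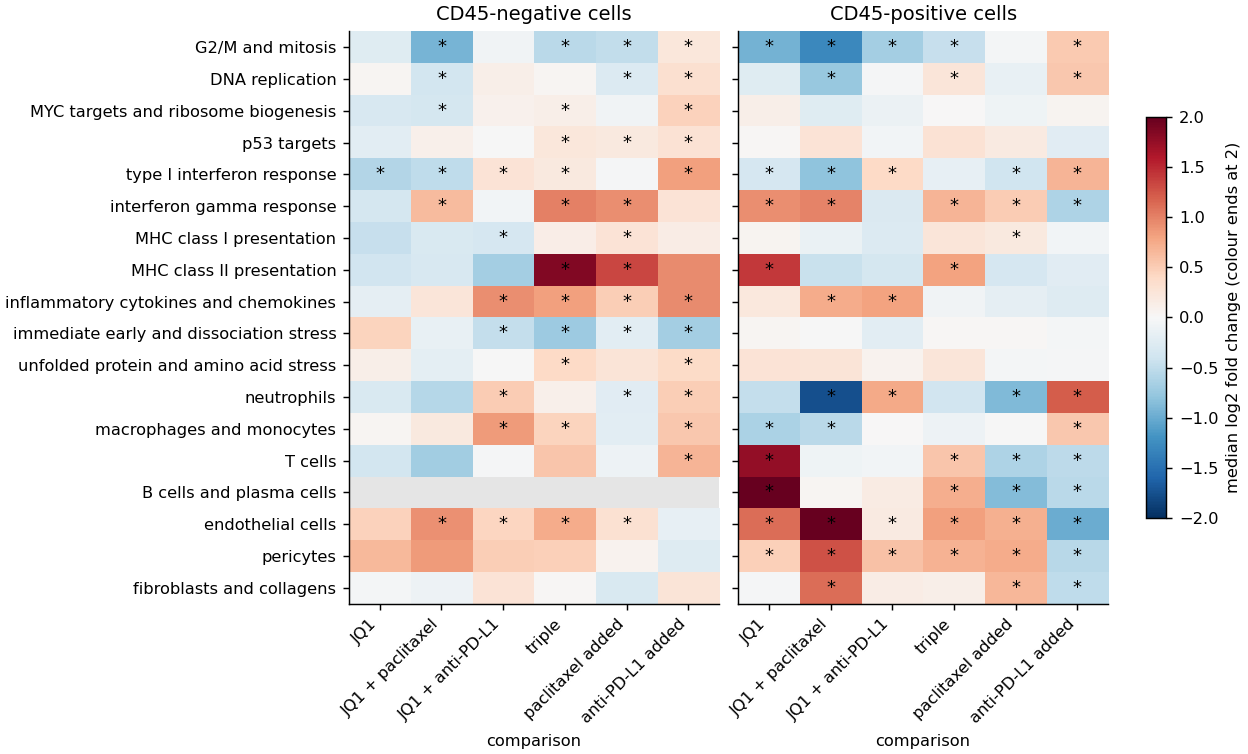
Median log2 fold change of 18 gene lists (lines of the map) in 6 comparisons (columns) for each fraction, with asterisks where camera's adjusted p at the preset correlation was under 0.05 and grey where fewer than 3 members were tested. Endothelial genes reach 2.20 for JQ1 with paclitaxel in the CD45-positive fraction, against 0.91 in the CD45-negative fraction, and mitotic genes −1.28 and −0.93.

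In CD45-positive cells the 4 JQ1 groups (n = 8) were set against vehicle (n = 2), and genes of vessel walls rose furthest. The endothelial genes Plvap (2.58 ± 0.17, adjusted p = 0.000564), Esam (2.51 ± 0.20, adjusted p = 0.00116) and Pecam1 (1.75 ± 0.21, adjusted p = 0.00989) rose. So did the basement membrane collagen genes Col4a1 (2.40 ± 0.35) and Col4a2 (2.17 ± 0.24), the pericyte genes Mcam (2.17 ± 0.20) and Rgs5 (1.62 ± 0.23), and Fabp4 (2.64 ± 0.31). The growth factor gene Ereg (2.21 ± 0.36) and the complement inhibitor gene Serping1 (2.14 ± 0.30) rose as well. The genes that fell furthest included the osteoclast and giant cell genes Slc9b2 (−3.80 ± 0.60), Atp6v0d2 (−3.41 ± 0.43) and Ocstamp (−2.71 ± 0.37), the macrophage genes Fcrls (−3.30 ± 0.30) and Apoc2 (−2.08 ± 0.29), and the monocyte chemokine receptor gene Ccr2 (−3.11 ± 0.44), with FAM109A (−1.93 ± 0.25) and Eno3 (−1.76 ± 0.32). Adjusted p for the 8 highest and 8 lowest ran from 0.000564 to 0.0477. Of 13 endothelial genes 4 rose, and 13 adjusted over the list alone (median 1.14, 4.56e-17, or 0.145 with an estimated correlation). Of 7 pericyte genes 2 rose, and 6 with 1 lower adjusted over the list alone (median 0.71, 2.58e-05), and of 13 fibroblast genes 2, Postn (1.47 ± 0.26) and Cd34 (1.04 ± 0.16; median 0.38, 0.00585). Of 22 mitotic genes 1 fell, Cdc20 (−1.2 ± 0.21), and 18 adjusted over the list alone (median −0.85, 1.34e-12). B cell (median 0.75, 5.35e-05), T cell (0.64, 0.000575) and cytotoxic effector genes (0.65, 0.000358) were higher, with the perforin gene Prf1 (1.09 ± 0.18, adjusted p = 0.0362) past the threshold. Most of the lymphocyte mean came from JQ1 alone: list levels, in mean log2(FPKM + 1), were 1.2 (T cells) and 0.946 (B cells) in vehicle, 2.98 and 3.17 in JQ1, 1.13 and 1.24 in JQ1 with anti-PD-L1, 1.13 and 0.929 in JQ1 with paclitaxel and 1.8 and 1.8 in the 3-drug group. Interferon gamma (0.61, 0.000596), tubulin (0.27, 0.00152), adipocyte (0.30, 0.018) and inflammatory genes (0.40, 0.018) were higher and erythroid genes lower (−2.41, 0.000352). Stmn1 fell by 0.77 ± 0.13 (adjusted p = 0.0379), against the median of its tubulin list, whose mean turned to −0.121 (camera adjusted p = 0.597) without the genes higher in the CD45-negative fraction. The 11 lists after the endothelial list had adjusted p = 0.145 to 0.779 with an estimated correlation. Hexim1 (0.90 ± 0.32, adjusted p = 0.221), Myc (−0.59 ± 0.19, adjusted p = 0.191), Cd274 (0.61 ± 0.70) and Ptprc (0.16 ± 0.21) were not past the threshold. Of 10340 genes 85 were called, 31 higher and 54 lower, or 46 and 33 with a pseudocount of 0.1 and 21 and 87 with no filter. The count was 3 without vehicle replicate 2, 128 without 3-drug replicate 1, 40 and 45 without JQ1 with anti-PD-L1 replicate 1 and 2, and 4 with relative depth as a covariate. Without vehicle replicate 1, or with a single value per mouse code, limma called 0, from 1656 genes with an unadjusted p under 0.05 in the full comparison.

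JQ1 alone in CD45-positive cells (n = 2 and 2) was marked by lymphocyte and vessel genes. The lymphocyte genes Fcmr (3.43 ± 0.59), Gimap6 (3.09 ± 0.42), Ets1 (3.04 ± 0.39) and Ccr7 (2.76 ± 0.49) rose beside Col4a1 (2.83 ± 0.44), with adjusted p from 0.0175 to 0.0401. Slc9b2 (−4.36 ± 0.76), Atp6v0d2 (−3.95 ± 0.54), Ccr2 (−3.77 ± 0.56), Fcrls (−3.56 ± 0.37) and Ocstamp (−2.80 ± 0.46) fell, with adjusted p from 0.00976 to 0.037. T cell genes had 1 of 17 past the threshold, Tcf7 (2.58 ± 0.38, adjusted p = 0.0245), and 14 adjusted over the list alone (median 1.76, camera adjusted p = 3.73e-10). B cell genes had 2 of 12, the survival receptor gene Tnfrsf13c (2.57 ± 0.45) and Fcer2a (2.22 ± 0.34), and 11 adjusted over the list alone (median 2.19, 3.73e-10). Endothelial genes had 4 of 13 higher, such as Plvap (2.63 ± 0.22) and Esam (2.26 ± 0.25), and 10 adjusted over the list alone (median 1.12, 3.73e-10), and mitotic genes 1 of 22 lower, Cdc20 (−1.53 ± 0.26), and 17 adjusted over the list alone (median −0.95, 3.82e-10). Cytotoxic effector (1.18, 3.99e-05), interferon gamma (0.93, 0.00144), MHC class II (1.41, 0.00147), pericyte (0.48, 0.00392), regulatory T cell (0.69, 0.0074) and dendritic cell genes (0.61, 0.0347) were higher, and macrophage (−0.63, 0.000563), erythroid (−2.91, 0.000572) and type I interferon genes (−0.34, 0.0218) lower. These 13 lists had adjusted p = 0.173 to 0.739 with an estimated correlation. NK cell genes had a median of 0.72 (camera adjusted p = 0.0529), with the cytokine receptor gene Il2rb (2.35 ± 0.33, adjusted p = 0.0205) higher. The mast cell, basophil and eosinophil list had fewer than 3 members expressed in either fraction, here only Kit (1.25 ± 0.36, adjusted p = 0.118). Prf1 (1.83 ± 0.23), Ciita (1.5 ± 0.21) and Fabp4 (2.64 ± 0.39) rose, while Hexim1 (1.06 ± 0.41, adjusted p = 0.197) and the histone genes (median −0.10) did not pass the threshold. JQ1 replicate 1, the library apart on the second component, carried more of the T cell signal: the T cell median was 0.959 without it and 2.71 without JQ1 replicate 2. The mean of the interferon gamma list turned from 0.87 to −0.09 without JQ1 replicate 1, and that of type I interferon genes was 0.0282 without replicate 2. A total of 108 genes was called, 63 higher and 45 lower (41 and 51 with no filter). Leaving out vehicle replicate 1 or 2 gave 0 by limma (2037 genes had an unadjusted p under 0.05 with all libraries), leaving out JQ1 replicate 1 gave 2, leaving out either JQ1 with anti-PD-L1 library gave 13, and relative depth as a covariate left 2.

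JQ1 with anti-PD-L1 in CD45-positive cells (n = 2 and 2) gave 3 calls, all lower, Cyp2s1 (−2.58, adjusted p = 0.00645), the osteoclast receptor gene Oscar (−2.11, adjusted p = 0.0147) and Rufy4 (−2.45, adjusted p = 0.0147), named after their values were seen. The vessel genes Esam (1.59 ± 0.25, adjusted p = 0.125), Mcam (1.29 ± 0.25) and Plvap (1.10 ± 0.22) and the growth factor gene Ereg (3.28 ± 0.46, adjusted p = 0.0908) stood highest without passing the threshold. FAM109A (−1.90 ± 0.32), Tsc22d1 (−1.47 ± 0.25), Fcrls (−2.17 ± 0.37) and Stmn1 (−0.93 ± 0.17) stood lowest and did not pass it either. Mitotic genes had a median of −0.68 (camera adjusted p = 1.7e-12), with 8 of 22 lower adjusted over the list alone. Inflammatory (0.80, 4.14e-06), endothelial (0.18, 1.77e-05), type I interferon (0.39, 0.00011), neutrophil (0.76, 0.00078), cytotoxic (0.72, 0.00131), pan-leukocyte (0.16, 0.00155), tubulin (0.32, 0.00384), pericyte (0.59, 0.0103) and adipocyte genes (0.30, 0.0421) were higher and erythroid genes (−1.54, 0.00384) lower. These 11 lists had adjusted p = 0.369 to 0.753 with an estimated correlation. The tubulin mean turned to −0.285 (camera adjusted p = 0.14) without the genes higher in the CD45-negative fraction. The 735 genes with an unadjusted p under 0.05 gave between 0 and 5 calls when 1 library was left out, and 0 with relative depth as a covariate.

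JQ1 with paclitaxel in CD45-positive cells (n = 2 and 2) had the strongest vessel signal. All 13 endothelial genes rose, over all genes and adjusted over the list alone, led by Plvap (4.13 ± 0.22, adjusted p = 0.000148), Esam (3.87 ± 0.25, adjusted p = 0.000318) and Pecam1 (2.87 ± 0.26, adjusted p = 0.00137). Their median was 2.20 (camera adjusted p = 1.6e-22, or 0.0953 with an estimated correlation). Fabp4 (4.49 ± 0.39, adjusted p = 0.0011), Col4a1 (4.30 ± 0.44) and Col4a2 (3.88 ± 0.30) rose with them. Pericyte genes had 5 of 7 higher, Mcam (3.58 ± 0.25), Rgs5 (2.91 ± 0.29) and the muscle filament gene Des (2.02 ± 0.31) among them, and 6 with 1 lower adjusted over the list alone (median 1.28, 2.56e-07). Fibroblast genes had 6 of 13 higher, such as Postn (2.43 ± 0.33) and Pdgfrb (2.12 ± 0.45), and 7 with 1 lower adjusted over the list alone (median 1.12, 2.82e-07), and the mesenchymal transition list (0.38, 0.0084) had Sparc (2.47 ± 0.42) past the threshold. Macrophage and monocyte genes fell, 4 of 18, such as Chil3 (−4.88 ± 0.94, adjusted p = 0.0247), Fcgr1 (−2.12 ± 0.49) and Ms4a7 (−1.86 ± 0.25; median −0.53, 0.0498), beside Ccr2 (−4.68 ± 0.56), Fcrls (−4.49 ± 0.37) and Atp6v0d2 (−3.87 ± 0.54). Neutrophil genes fell, 3 of 18, or 7 adjusted over the list alone, such as Retnlg (−4.17 ± 0.73; median −1.76, 0.00242), and pan-leukocyte genes 2 of 12, or 5 adjusted over the list alone, such as the adaptor gene Tyrobp (−0.74 ± 0.17; median −0.45, 0.00176). Mitotic genes fell, 11 of 22, or 19 adjusted over the list alone, such as Ccnb2 (−2.61 ± 0.59) and Ube2c (−2.25 ± 0.51; median −1.28, 6.52e-12), and replication genes had 8 of 20 lower adjusted over the list alone (median −0.76, 9.9e-05). Tubulin genes had 4 of 15 higher and 1 lower, Tubb4b (1.75 ± 0.30) and Stmn1 (−1.2 ± 0.17) in front, and 8 with 1 lower adjusted over the list alone (median 0.68, 5.63e-06, and mean −0.0808, 0.921, without the genes higher in the CD45-negative fraction). Type I interferon genes had 3 of 25 lower, or 7 adjusted over the list alone, such as Xaf1 (−1.38 ± 0.31; median −0.81, 0.00334). Interferon gamma (1, 4.46e-05), inflammatory (0.74, 0.00258), adipocyte (0.34, 0.0382) and cytotoxic genes (0.46, 0.0441) were higher, with Iigp1 (2.95 ± 0.65) and Ccl3 (1.87 ± 0.37) past the threshold, and erythroid genes (−1.98, 0.0206) lower. The 15 lists after the endothelial list had adjusted p = 0.172 to 0.638 with an estimated correlation. The inflammatory mean was −0.13 without JQ1 with paclitaxel replicate 2. B cell genes (median 0.04, mean −0.02) had no call, and their mean was −0.90 without JQ1 with paclitaxel replicate 1 and 0.83 without replicate 2. Of 58 histone genes 12 fell and 0 rose (median 0.11), and 0 fell with relative depth as a covariate. The p53 target and growth factor gene Gdf15 rose by 2.40 ± 0.29 (adjusted p = 0.0045). The 500 calls comprised 163 higher and 337 lower, and 185 higher and 241 lower of 426 after rescaling. The count was 17 and 38 without vehicle replicate 1 and 2 (14 and 26 higher), 231 and 54 without JQ1 with paclitaxel replicate 1 and 2 (32 of the 54 higher), and 265 and 263 without JQ1 with anti-PD-L1 replicate 1 and 2. It was 254 without the genes higher in the CD45-negative fraction, 4 with relative depth as a covariate, and 0 by limma with a single value per mouse code (2205 genes had an unadjusted p under 0.05 in the full comparison).

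**Figure D5:**
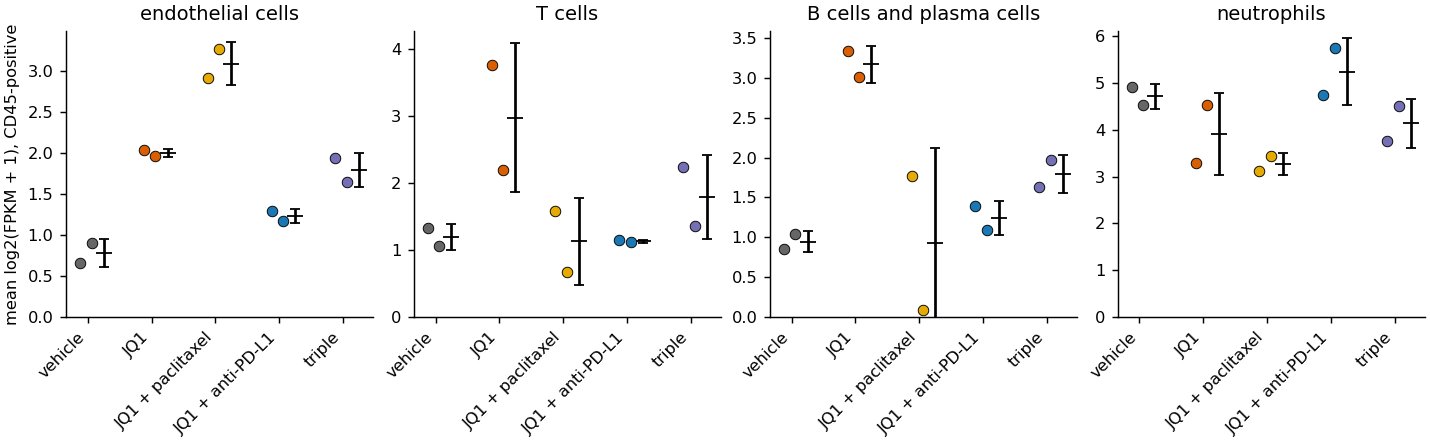
Mean log2(FPKM + 1) of the endothelial, T cell, B cell and neutrophil lists in each CD45-positive library, grouped by treatment, with the group mean and SD as line and bar. The median endothelial fold change against vehicle is 2.20 for JQ1 with paclitaxel, 1.12 for JQ1, 0.81 for the 3-drug group and 0.18 for JQ1 with anti-PD-L1.

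The 3-drug group in CD45-positive cells (n = 2 and 2) kept vessel genes in front, Plvap (2.48 ± 0.22, adjusted p = 0.00591), Esam (2.33 ± 0.25, adjusted p = 0.0153), Emcn (1.80 ± 0.23, adjusted p = 0.0313), Mcam (1.80 ± 0.25, adjusted p = 0.0394) and Timp3 (1.79 ± 0.25, adjusted p = 0.0394). The macrophage gene Fcrls (−2.97 ± 0.37, adjusted p = 0.028) and Tsc22d1 (−1.82 ± 0.25, adjusted p = 0.0394) fell. Endothelial genes had 3 of 13 higher, and 8 adjusted over the list alone (median 0.81, camera adjusted p = 1.52e-11), and pericyte genes 1 of 7, and 4 with 1 lower adjusted over the list alone (0.70, 0.000702). Interferon gamma (0.68, 0.000343), B cell (0.72, 0.000681), T cell (0.55, 0.00177), MHC class II (0.81, 0.00433), cytotoxic (0.49, 0.0111), replication (0.25, 0.0167), regulatory T cell (0.53, 0.0394), adipocyte (0.31, 0.0446) and tubulin genes (0.18, 0.0446) were higher, and erythroid (−3.22, 8.06e-06) and mitotic genes (−0.46, 0.000249) lower. These 13 lists had adjusted p = 0.298 to 0.616 with an estimated correlation. Of uncalled lists, immediate early genes had a mean of −0.13 with all libraries and 0.51 without 3-drug replicate 1, and type I interferon genes −0.17 with all and 0.29 without 3-drug replicate 2. The inflammatory mean was −0.81 without 3-drug replicate 1. The 14 calls comprised 5 higher and 9 lower (8 and 3 with a pseudocount of 0.1), with 903 genes at an unadjusted p under 0.05. The count was 6 and 3 without 3-drug replicate 1 and 2, 7 without either JQ1 with anti-PD-L1 library, 3 with relative depth as a covariate and 0 by limma without either vehicle library.

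Between CD45-positive groups that share controls, JQ1 alone and JQ1 with paclitaxel had 19 higher and 42 lower genes in common, against 0.993 and 1.47 for independent lists. Across genes r was 0.711 (covariance 0.265), against 0.501 (covariance 0.0741) in simulated groups without effect. Against separate vehicle libraries r was 0.455 or 0.562 (covariance 0.2 or 0.226), and part of the overlap of called genes may again come from the shared controls.

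Paclitaxel added to JQ1 in CD45-positive cells (n = 4 and 4) gave 4 calls. The endothelial genes Emcn (1.52 ± 0.17) and Plvap (1.44 ± 0.15) rose, both with adjusted p = 0.0254. Cyp4b1 (1.71, adjusted p = 0.0352) rose and the microRNA gene Mir6236 (−1.93, adjusted p = 0.0254) fell, both named after their values were seen. Timp3 (1.37 ± 0.17, adjusted p = 0.0537), Esam (1.17 ± 0.18), Mcam (1.05 ± 0.18) and Serpine2 (1.16 ± 0.20) came next, and Napsa (−1.07 ± 0.14), Cytip (−1.05 ± 0.14), Stfa2l1 (−1.5 ± 0.24) and Hist1h4d (−1.17 ± 0.19) were lowest, without passing the threshold. Endothelial genes had 11 of 13 higher adjusted over the list alone (median 0.72, 2.17e-17, or 0.167 with an estimated correlation). Pericyte (0.74, 5.21e-06), tubulin (0.28, 0.000156), fibroblast (0.67, 0.000156), interferon gamma (0.51, 0.000156), MHC class I (0.20, 0.0276) and epithelial genes (0.50, 0.0347) were higher, and B cell (−0.87, 2.87e-06), pan-leukocyte (−0.32, 2.87e-06), neutrophil (−0.89, 5.21e-06), type I interferon (−0.40, 9.92e-05), T cell (−0.62, 0.000156) and cytotoxic genes (−0.36, 0.019) lower. These 12 lists had adjusted p = 0.185 to 0.723 with an estimated correlation. T and B cell levels were lower with paclitaxel only without antibody (2.98 to 1.13 and 3.17 to 0.929), and higher with antibody (1.13 to 1.8 and 1.24 to 1.8). Fibroblast levels were higher only without antibody. The MHC class I mean was −0.08 without JQ1 replicate 2, and the inflammatory mean turned from −0.12 to 0.24 without JQ1 with paclitaxel replicate 1. Counts ran from 0 to 8 when 1 library was left out, 8 of them without JQ1 with paclitaxel replicate 1, and 977 genes had an unadjusted p under 0.05 in limma.

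Anti-PD-L1 added to JQ1 in CD45-positive cells (n = 4 and 4) gave falls in vessel genes and rises in myeloid genes. Col4a1 (−2.33 ± 0.31), Col4a2 (−2.02 ± 0.21, adjusted p = 0.0322), Fabp4 (−1.84 ± 0.28), Eng (−1.69 ± 0.30) and Pecam1 (−1.43 ± 0.18) fell with Plvap (−1.59 ± 0.15, adjusted p = 0.027) and Mcam (−1.25 ± 0.18). Among the 8 lowest were also Rgs16 (−1.36 ± 0.20), Sema3f (−1.24 ± 0.23) and Leng8 (−1.18 ± 0.18). Dmkn (2.51 ± 0.36), the myeloid genes Ms4a4c (1.88 ± 0.29), Mcemp1 (1.37 ± 0.21), Ms4a7 (1.33 ± 0.18) and Trem3 (1.19 ± 0.19), the complement gene Cfp (1.32 ± 0.21), the cytokine gene Il18 (1.31 ± 0.19) and the antiviral gene Oas1a (1.31 ± 0.20) rose, all 8 with adjusted p = 0.0433. Ccr2 rose by 2.23 ± 0.39 (adjusted p = 0.0483) with libraries overlapping. Endothelial genes had 6 of 13 lower, and 13 adjusted over the list alone (median −0.99, 1.47e-14), and pericyte genes 2 of 7, and 5 adjusted over the list alone (−0.55, 6.43e-05). Replication genes had 13 of 20 higher (0.55, 2.21e-08), type I interferon genes 12 of 25 (0.69, 7.34e-07), neutrophil genes 8 of 18 (1.22, 4.01e-06), macrophage genes 9 of 18 (0.54, 3.27e-05), pan-leukocyte genes 7 of 12 (0.39, 6.43e-05) and mitotic genes 5 of 22 (0.53, 1.7e-06), all adjusted over the list alone. Interferon gamma (−0.62, 0.000138), fibroblast (−0.51, 0.00021), T cell (−0.52, 0.000532), B cell (−0.54, 0.00244), mesenchymal transition (−0.40, 0.0106) and epithelial genes (−0.82, 0.0332) were lower, and alternatively activated macrophage (0.67, 0.0103) and skeletal muscle genes (0.52, 0.0106) higher. These 16 lists had adjusted p = 0.241 to 0.595 with an estimated correlation. T and B cell levels were lower with antibody only against JQ1 alone, and higher against JQ1 with paclitaxel (1.13 to 1.8 and 0.929 to 1.8). Fibroblast levels were lower mainly against JQ1 with paclitaxel. The epithelial mean turned to 0.107 (camera adjusted p = 0.941) without the genes higher in the CD45-negative fraction. Hexim1 (−0.51 ± 0.29, adjusted p = 0.384) was not past the threshold, and 1 of 58 histone genes rose (median −0.16). The 86 calls comprised 50 higher and 36 lower. Limma called 0 genes without vehicle replicate 1 or 2, 3-drug replicate 1, JQ1 with paclitaxel replicate 2, JQ1 replicate 1, or either JQ1 with anti-PD-L1 library, and 0 with relative depth as a covariate or no filter (1936 had an unadjusted p under 0.05 in the full comparison). The count was 1 without JQ1 with paclitaxel replicate 1, 10 without JQ1 replicate 2 and 46 without the genes higher in the CD45-negative fraction.

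The interaction of paclitaxel and anti-PD-L1 in CD45-positive cells gave 0 genes in limma, with 1070 at an unadjusted p under 0.05. The median of all genes was 0.16 in this contrast and −0.001 after rescaling of the libraries, so values are read against that shift. Lymphocyte genes stood highest, Gimap6 (4.04 ± 0.59), Tspan13 (1.93 ± 0.31), the lymphotoxin gene Ltb (2.91 ± 0.47) and H2-DMb2 (3.52 ± 0.60), each with adjusted p = 0.205, and Timp1 (−2.34 ± 0.44), S100a4 (−1.54 ± 0.33), Olr1 (−2.43 ± 0.53) and Errfi1 (−1.45 ± 0.33) lowest. T cell (median 2.42, 9.61e-12), B cell (2.85, 2.67e-10) and MHC class II genes (3.01, 6.98e-09) had 17 of 17, 10 of 12 and 9 of 10 higher adjusted over the list alone. Camera called 23 lists in all, with adjusted p = 0.273 to 0.615 with an estimated correlation. The count was 10 without JQ1 with paclitaxel replicate 1 and 1 without 3-drug replicate 1 or JQ1 replicate 1.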

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

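The tests of weaker BET inhibition, scaling, more endothelial cells, a single library and handling were chosen after the result was seen, and the readings of both BET tests and of the lymph node test were tightened after their values were seen.

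All 34 flagged results came from the interaction test of paclitaxel and anti-PD-L1, a difference between groups. In CD45-negative cells it flagged 1 gene and 10 lists, with mean log2 differences of 0.235 (G2/M and mitosis), 0.459 (DNA replication), 0.256 (MHC class I), 1.96 (MHC class II), 0.792 (unfolded protein and amino acid stress), −0.723 (neutrophils), −0.516 (macrophages), −0.887 (alternatively activated macrophages), −0.890 (inflammatory cytokines) and −2.13 (erythroid). In CD45-positive cells it flagged 23 lists. Those above 0 were MYC targets 0.410, G2/M and mitosis 0.697, DNA replication 0.671, interferon gamma 0.974, MHC class I 0.660, MHC class II 2.48, T cells 2.52, T cell checkpoint 1.13, regulatory T cells 1.39, NK cells 1.33, B cells 2.80, dendritic cells 0.965 and pan-leukocyte 0.630. Those below 0 were tubulins −0.468, type I interferon −0.244, macrophages −0.133, inflammatory cytokines −1.13, fibroblasts −1.08, endothelial −0.531, pericytes −0.571, epithelium −0.598, erythroid −2.35 and mesenchymal transition −0.814. No list was called with an estimated correlation. In CD45-positive cells most of the T and B cell differences came from the high levels of JQ1 alone, not from the 3-drug group.

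In CD45-negative cells both groups given anti-PD-L1 lay near vehicle on the first principal component, though the 3-drug group lay apart from it on the second. Leukocyte carry-over as the whole cause was argued against, since 45.1% of the called genes changed by over 0.5 without being higher in the CD45-positive table, and so was scaling, since 2790 genes were called after rescaling. Weaker BET inhibition in the antibody groups cannot be told apart from other effects of the antibody: 93.5% of the 1592 genes called for JQ1 had the opposite sign in the 3-drug group minus JQ1 with paclitaxel, but this share restates the pattern. In CD45-positive cells of the same tumours the share was 60.2% (65 of 108 genes), and histone genes there, which JQ1 alone did not raise (median −0.101), had a median of −0.155 for anti-PD-L1 added, with 1 of 58 higher by limma, so neither decides. With JQ1 and paclitaxel 12 of the 58 fell there, while 28 of 55 rose in CD45-negative cells. Handling or housing of whole groups stays open too, as 0 leading codes of the mouse codes were shared by any pair of groups.

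Endothelial and pericyte genes rose with JQ1 and paclitaxel in CD45-positive cells. Carry-over of the CD45-negative fraction as a whole would raise its other genes alike, but the 300 genes at least 8 times higher there had a median of 0.243, against 2.20 for the endothelial list. As part of the cause it stays open: fold changes in CD45-positive minus CD45-negative cells had medians of 1.67 for endothelial, 2.06 for pericyte, 1.07 for fibroblast, 1.42 for epithelial and 1.03 for adipocyte genes, and of 0.618, 0.698 and 0.875 for genes at least 8, 16 and 32 times higher in CD45-negative cells. More endothelial cells with the same carry-over would show in CD45-negative cells, where the endothelial median was 0.915, against 2.51 for the same 10 genes in CD45-positive cells. A combination of the 2, or endothelial cells held back by the beads, stays open, and no biological explanation was tested.

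T and B cell genes were higher with JQ1 alone in CD45-positive cells. A single library as the whole cause was argued against, since without JQ1 replicate 1 the medians were 0.959 and 2.19 and the higher camera adjusted p 2.08e-05, though adjusted p = 0.596 and 0.486 with an estimated correlation. Lymph node tissue cannot be told apart from lymphocytes in the tumour: stroma and vessel genes of lymph nodes reached 0.187 in the JQ1 CD45-negative libraries and 0 to 0.501 in the others, near the floor. In CD45-positive JQ1 replicate 1 they reached 1.06, with Glycam1 at 2.43 and Ccl21a at 1.55, but in replicate 2 they were at 0.0159, the lowest of the 10 libraries, with both genes at 0, while 8 genes of naive lymphocytes stood at 2.53, against 1.63 and 1.35 in vehicle.

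Other splits of the libraries into groups of matching size were also run. For paclitaxel added, 1 of 100 splits of the CD45-negative libraries, the real one, called as many genes (384, the next 73), and for anti-PD-L1 added again 1 of 100 (2691, the next 84). These splits exchange single libraries, while JQ1 and JQ1 with anti-PD-L1 hold 1 mouse code each, and with a single value per mouse code the counts were 7 and 738. In the CD45-positive fraction the real split was matched or exceeded for paclitaxel, 3 of 34 with up to 352 genes, so its 4 calls are not told from sample structure, and for anti-PD-L1 1 of 34 splits, the real one, reached 86, with the next at 82.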

How the results depend on the processing

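Leaving out the genes of the other fraction and relative depth as a covariate were chosen after the results were seen. Of the named-gene values called with all libraries, 6134 kept direction and side of the threshold, 2306 lost the call and 0 reversed, and of the list values 3053 kept both, 666 lost the call and 12 reversed. Of those not called, 137 gene and 297 list values passed the threshold and 8 list values reversed. Every list call was lost with an estimated correlation. Leaving out 1 of 2 libraries leaves a lone sample, assumed to vary like the other groups. No paired analysis was possible because the labels give no replicate numbers that pair tumours across groups. Absolute depth was unknown, so low genes could not be weighted by their counts, and a covariate of relative depth cost 1 of 7 or 5 residual degrees of freedom. With it 321 genes were called for CD45-negative JQ1, 291 of them among the 1592. Unless said otherwise, the cause was not tested.

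Counts of called genes that moved by over 1.5 times follow, in the order given. In CD45-negative cells the pseudocount of 0.1 gave JQ1 with anti-PD-L1 15, 3-drug 38, interaction 0. With no filter, where more genes were tested, 3-drug 52, paclitaxel added 120, interaction 2. Rescaled, interaction 2. With correlation within mouse codes, JQ1 with anti-PD-L1 154, 3-drug 330, interaction 2. With a single value per mouse code, which leaves fewer samples, JQ1 21, JQ1 with anti-PD-L1 1, JQ1 with paclitaxel 274, 3-drug 5, all JQ1 groups 10, paclitaxel added 7, anti-PD-L1 added 738. Without the genes of the other fraction, JQ1 with anti-PD-L1 72, interaction 2. With the depth covariate, JQ1 321, 3-drug 48, all JQ1 groups 332, paclitaxel added 231, interaction 7. CD45-positive: with pseudocount 0.1, JQ1 68, JQ1 with anti-PD-L1 0, paclitaxel added 2, anti-PD-L1 added 25. With no filter, JQ1 with anti-PD-L1 21, 3-drug 23, paclitaxel added 0, anti-PD-L1 added 0. With correlation within mouse codes, which was negative and so narrowed the errors, JQ1 1823, JQ1 with anti-PD-L1 86, JQ1 with paclitaxel 1307, 3-drug 77, all JQ1 groups 1069, paclitaxel added 36, anti-PD-L1 added 775 and interaction 3. With a single value per mouse code limma called 0 in the 7 comparisons other than the interaction. Without the genes of the other fraction, JQ1 with paclitaxel gave 254 and anti-PD-L1 added 46. With the depth covariate, JQ1 gave 2, JQ1 with anti-PD-L1 0, JQ1 with paclitaxel 4, 3-drug 3, all JQ1 groups 4, paclitaxel added 0 and anti-PD-L1 added 0.

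Leaving out 1 library gave these ranges, with fewer samples by construction. CD45-negative: JQ1 423 (without JQ1 replicate 1) to 1744, JQ1 with anti-PD-L1 1 (without its replicate 1) to 104, JQ1 with paclitaxel 530 (without vehicle replicate 2) to 1886, 3-drug 5 (without vehicle replicate 1) to 322, all JQ1 groups 57 (without vehicle replicate 2) to 928, paclitaxel added 8 (without JQ1 with anti-PD-L1 replicate 1) to 458, anti-PD-L1 added 1567 (without JQ1 with anti-PD-L1 replicate 2) to 2879, interaction 0 to 4. Every highest count came without JQ1 with paclitaxel replicate 3, except 1886 (without 3-drug replicate 3) and 458 (without JQ1 with paclitaxel replicate 2). CD45-positive: JQ1 0 to 121, JQ1 with anti-PD-L1 0 to 5, JQ1 with paclitaxel 17 to 548, 3-drug 0 to 15, all JQ1 groups 0 to 128, paclitaxel added 0 to 8, anti-PD-L1 added 0 to 91, interaction 0 to 10. The lowest came without vehicle replicate 1 for JQ1, JQ1 with paclitaxel and all JQ1 groups.

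Lists whose direction in camera reversed had these mean log2 fold changes. Without the genes of the other fraction, which takes members out of a list: CD45-negative inflammatory cytokines −0.349 in JQ1 with anti-PD-L1, and in CD45-positive cells tubulins −0.285 in JQ1 with anti-PD-L1, −0.121 in all JQ1 groups and 0.248 in the interaction, and epithelium 0.107 for anti-PD-L1 added. With the depth covariate: CD45-negative macrophages −0.8 in JQ1 and −0.119 in all JQ1 groups, and endothelial 0.744 in the interaction. Leaving out 1 CD45-positive library gave interferon gamma −0.0858 to 1.83 in JQ1, B cells −0.897 to 0.827 in JQ1 with paclitaxel, in the 3-drug group type I interferon −0.622 to 0.288, inflammatory −0.814 to 0.669 and immediate early −0.777 to 0.514, for paclitaxel added MHC class I −0.076 to 0.422 and inflammatory −0.486 to 0.255 (0.242 without JQ1 with paclitaxel replicate 1), and in the interaction type I interferon −0.699 to 0.21, interferon gamma 0.0154 to 1.93 and immediate early −0.465 to 0.826. The ends came without 3-drug, JQ1 or JQ1 with paclitaxel replicate 1 or 2, the groups in these contrasts.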

Other observations

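Ftl1 and Trp53, chosen after their values were seen, differed between the CD45-negative groups. Ftl1 was higher and Trp53 lower in the groups where Hexim1 was high. Mean FPKM of Ftl1, a ferritin gene whose pseudogenes share reads, was 9210 in vehicle, 14300 in JQ1, 9140 in JQ1 with anti-PD-L1, 15200 in JQ1 with paclitaxel and 7950 in the 3-drug group, and that of Trp53 72.7, 38.7, 60, 37.6 and 60.5. Mean Hba-a1 was 63 FPKM in vehicle and under 1 in the other groups but JQ1 with anti-PD-L1, whose libraries stood at 0.0579 and 28.7 FPKM.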
